A study of Mus musculus with 30 samples.

How the data were processed

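RNA was sequenced from mouse CGR8 embryonic stem cells (ESC), from embryoid bodies made from them (EB8, given retinoic acid while they formed) and from neurons at 7 days in vitro (DIV7), after polyA selection and a stranded library protocol changed to give longer inserts, per the labels' protocols. The parental line (WT) and 4 edited lines were sampled at each of the 3 stages with 2 replicates, which gave 30 libraries in 15 groups. The edited lines are called here by their labels: Puf60_mEx5_HOM is labelled as lacking exon 5 of Puf60, Puf60_pEx5_HOM and Puf60_pEx5_HET carry constitutive exon 5 on both alleles or on 1, and Rbm38KO carries a deletion in Rbm38. The series text speaks of independent clones but the labels do not say which library came from which clone, so the p-values measure only the spread between these libraries, part of which can be technical.

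The authors deposited a table of genes with 1 RPKM value per group, per the file headers, with no value per library. The same table holds the authors' log2 fold changes, p-values and FDR for each edited line against WT at each stage, per the file headers. A second deposited table gives the authors' percent spliced in (PSI) as 1 value per group, treated here as a score because alternative splice sites exceed 100, and TRUE or FALSE calls of the authors, which are of another kind than a measurement. Of its columns, 2 named for Puf60_mEx5_HOM at DIV7 differ in 0 of the 304953 events with a value in both, and no column is named for WT at DIV7, per the file headers. The third deposited table is vast-tools output with PSI in percent per library, the length of each alternative sequence and, per the file headers, quality strings of another kind that hold read numbers. The submitters' processing notes name Salmon 0.14.1, edgeR and the mouse build mm10 without saying what each was used for. The criteria of the authors' calls, the way replicates were combined and whether counting used strand are not given in the sources used here.

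Because no expression value per library was in the tables, expression was tested on spliced reads: for every gene, the exon-exon junction reads in the quality strings of its retained-intron events were summed per library. This measure was chosen after the tables were seen. It covers 189118 introns of 25626 genes and misses genes without introns, and overlapping genes that share a junction cannot be separated. The libraries held 23204150 to 38571969 such reads. Counts were scaled to CPM with median-of-ratios factors, genes with at least 1 CPM in at least 2 libraries were kept (13938 genes), and log2(CPM + 1) was fitted with limma (trend and robust settings) on all 30 libraries with 15 group means, which leaves 15 residual degrees of freedom. Fold changes are on that scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change. A fold against a group with no read is a lower bound from 3 reads over the group and covers counting error only. Simulated data (Puf60_pEx5_HOM at DIV7, dispersion 0.02) overstate power for noisier genes. The fit called 0% of genes changed by 0.5 log2, 36% at 1, 100% at 1.5 and 2, with 0 false calls among 13871.

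Splicing was tested on log ratios of inclusion and exclusion reads, with 1 read added to each, for events with at least 10 reads in every library of a stage. An event was called at an adjusted p under 0.05 and a PSI difference of at least 10 points. This planned fit covered 309671 events at ESC, 331185 at EB8, 322752 at DIV7 and 292202 for the WT stages. In simulated data for DIV7 it recovered 0% of changed events at any size tried among 322897 events. A read-weighted fit was therefore added: events with a mean PSI of 5 to 95, weighted by their reads and by the over-dispersion between replicates. It was chosen after the counts of the planned fit had been seen, and its settings were picked among many tried on simulated data. It covered 17949, 23570, 22206 and 17966 events, recovered 18% of simulated differences of 15 points, 50% at 20, 58% at 25 and 78% at 30, and made 2 false calls among 23346 events. Counts from both fits are given side by side. Microexons are exons of 3 to 27 nt, compared with longer cassette exons by Fisher's exact test.

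Before the data were examined, the groups, the comparisons, the tests of expression differences, 29 gene lists (cell types of the course from stem cell to neuron, other lineages, stress and signalling responses, imprinted genes and splicing factors) and the rule for named genes were fixed. The rule takes Puf60 and Rbm38, the 4 genes that rose and the 4 that fell most per edited line and stage (8 and 8 for WT between stages) among called genes with libraries that do not overlap and at least 5 RPKM in the higher group, up to 3 called members per gene list, genes called in the same direction at all 3 stages, exon 5 of Puf60, and the 3 cassette exons or microexons that rose and the 3 that fell most with at least 20 reads. Predicted gene symbols were left out, and not every gene or exon the rule gives is named in the text. RPKM for this rule came from the authors' deposited table, matched by symbol for 13721 of the 13938 genes. Lists were tested against all other genes with camera (limma, preset correlation 0.01), adjusted over 489 tests. Counts of members adjusted over the list alone are given where they differ. Of 156 list calls, 0 held with a correlation estimated from the libraries and 91 with fry (limma), which tests whether a list moves on balance 1 way and does not compare it with other genes. A pair of lists made from the data (the 500 genes that rose and the 500 that fell most from ESC to DIV7 in lines outside the comparison) were chosen on these samples and are not independent evidence of direction. The markers of 2-cell-like cells and the mitochondrial transcripts had too few measured members to test.

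Whether an edited line's effect differed between stages was tested as an interaction in the same fit, at an adjusted p under 0.05 with no fold minimum. Replicate letters are not said to pair libraries, but at ESC libraries with the same letter deviated together in all 10 pairs of groups (correlations 0.321 to 0.529), so at ESC the value with the letter as a block is given beside a result it moves. At EB8 and DIV7 5 of 10 and 4 of 10 pairs were above 0.1 (correlations -0.258 to 0.624 and -0.21 to 0.603), so not every pair was, and the block is given with the other settings there. Within each group, the 2 libraries differed by more than sampling noise (chi-square per gene 11.9 to 35.6), which repeat preparations of 1 RNA can show as well, so each was counted as 1 library and its independence was not tested. Alternatives tried were quantile scaling, scaling to the total, no filter, a pseudocount of 0.1, no fold minimum, no trend, voom weights, a replicate block, the libraries of 1 stage alone, each library left out, other read minimums and PSI differences, and the authors' own calls. Exon 5 of Puf60 was matched by coordinates to GENCODE M21 on mm10: 3 events coincide with an exon numbered 5 in some transcript, and the 51-nt simple cassette exon was taken after the values were seen because it follows the genotype labels (the other 2 events lie at 99.22 to 100% and 99.86 to 100% in all libraries). Event counts in the vast-tools table were 188941 cassette exons, 3652 microexons, 155678 alternative 3' sites and 123938 alternative 5' sites, of which 115732 first sites of an event were left out. R 4.3.3, limma 3.58.1, data.table (1.17.8), arrow 21.0.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.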

Results

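Spliced RNA was measured in WT CGR8 cells and 4 edited lines at 3 stages of neuronal differentiation: embryonic stem cells (ESC), embryoid bodies (EB8) and neurons (DIV7). Each of the 15 groups had 2 libraries, so n = 2 for every mean ± SD and every fold change. Depth was 28375996 to 38571969 spliced reads per library at ESC, 26152711 to 30675968 at EB8 and 23204150 to 28655479 at DIV7. Expression is given as normalised spliced read counts (CPM), and changes as log2 fold changes ± SE from limma with their Benjamini-Hochberg adjusted p-values. For a gene said to rise or fall, both libraries of 1 group lay beyond both of the other unless stated.

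The edited exon was examined first. Exon 5 of Puf60, a splicing factor that binds pyrimidine tracts at 3' splice sites, is a 51-nt coding exon. In WT its inclusion was 21.6 ± 1.2% (SD, n = 2) at ESC, 26.5 ± 0.57% at EB8 and 43.4 ± 0.74% at DIV7. In Puf60_pEx5_HOM inclusion was 98.6 ± 0.45%, 95.2 ± 1.8% and 94 ± 1.2% at these stages, and in Puf60_pEx5_HET 49.2 ± 0.12%, 52.3 ± 2.9% and 62.5 ± 3.4%. In Puf60_mEx5_HOM it was 8.76 ± 1.8%, 12.6 ± 0.53% and 11.4 ± 2.2%, which is above 0 in the line labelled as lacking the exon. The intron spanning the exon had a PSI of 13.3 ± 6.7%, 13.4 ± 0.71% and 9.34 ± 3.9% in Puf60_mEx5_HOM against 1 ± 0.064%, 2.58 ± 0.15% and 2.51 ± 0.014% in WT. In Rbm38KO inclusion was 23.2 ± 0.34%, 25.8 ± 2.5% and 46.8 ± 2.2%, and the read-weighted limma fit gave adjusted p of 0.962, 0.97 and 0.999 against WT. The same fit gave an adjusted p of 0.000923 for the increase of 16.9 points in WT from EB8 to DIV7, with both DIV7 libraries above both EB8 libraries. Against WT it gave changes of 77.1, 68.7 and 50.5 points in Puf60_pEx5_HOM (adjusted p = 1.1e-09, 7.83e-10 and 1.46e-08) and of 27.7, 25.8 and 19.1 points in Puf60_pEx5_HET (adjusted p = 0.00972, 0.0218 and 0.261). In Puf60_mEx5_HOM the changes were -12.8, -13.9 and -32 points (adjusted p = 0.154, 0.0253 and 2.92e-05). The planned limma fit called the exon at ESC and EB8 in Puf60_pEx5_HOM (adjusted p = 0.00273 and 0.0166). Each library's value rests on 673 to 2577 reads.

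**Figure D1:**
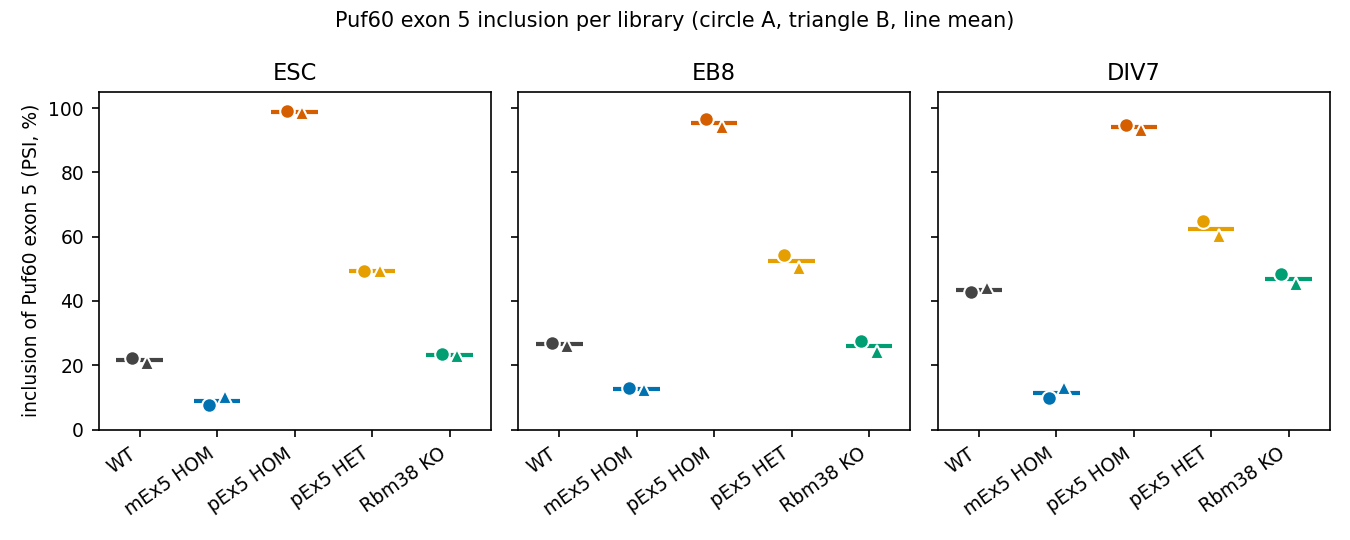
Inclusion of Puf60 exon 5 (percent spliced in, y axis) in each of the 30 libraries by stage and genotype, with circles for replicate A, triangles for replicate B and lines for the mean. Puf60_pEx5_HOM libraries sit between 93.15 and 98.97%, WT libraries between 20.71 and 43.95%, and Puf60_mEx5_HOM libraries between 7.49 and 13.01%.

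Puf60 itself was lower in Puf60_mEx5_HOM than in WT at all 3 stages: 218 ± 6.45 CPM against 336 ± 11.4 at ESC (-0.62 ± 0.07, adjusted p = 1.64e-05), 241 ± 16 CPM against 327 ± 11.4 at EB8 (-0.44 ± 0.07, adjusted p = 0.000195) and 173 ± 10 CPM against 253 ± 14.9 at DIV7 (-0.55 ± 0.07, adjusted p = 8.71e-05). These changes are under 2-fold. In the other lines Puf60 changed by -0.13 to 0.19 on the log2 scale. Rbm38, an RNA-binding protein known as a p53 target, had 0 spliced reads in all 6 Rbm38KO libraries. Against the WT levels of 85.4 ± 2.83, 39.6 ± 2.98 and 9.8 ± 1.79 CPM this is at least 1630-fold lower at ESC, 931-fold at EB8 and 172-fold at DIV7, from a floor of 3 reads over the group. These bounds hold for spliced reads alone. The authors' deposited table, on another measure, gave smaller log2 changes of -4.39, -3.51 and -1.91 for Rbm38 at these stages.

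Puf60_mEx5_HOM also lacked transcripts of the Y chromosome. Eif2s3y, Ddx3y, Uty, Uba1y and Kdm5d had 0 reads in its 6 libraries and 8463, 6219, 3734, 3010 and 1332 reads in the 6 WT libraries. Eif2s3y, the Y-linked copy of a translation initiation factor, was at least 1570-fold lower at ESC, 701-fold at EB8 and 486-fold at DIV7, and Ddx3y, a Y-linked RNA helicase, at least 792-, 623- and 553-fold. Each has an X-linked homolog that could not be excluded as a source of shared reads, but the count of 0 leaves none. Mid1, a ubiquitin ligase gene annotated on chromosome X, fell in the same line to 2.55 ± 0.373 CPM against 297 ± 8.16 at ESC (-6.40 ± 0.25, adjusted p = 3.32e-12). It changed by -4.20 ± 0.25 at EB8 (adjusted p = 4.15e-09) and -5.32 ± 0.25 at DIV7 (adjusted p = 5.95e-11).

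To describe the course of differentiation, WT embryoid bodies were compared with WT stem cells. Pluripotency genes fell together: 0 of 26 measured members rose and 26 fell. Their median was -4.97 (camera adjusted p = 1.57e-10, or 0.52 with an estimated correlation). Pou5f1, a core pluripotency transcription factor, fell from 1750 to 5.32 CPM (-8.14 ± 0.84, adjusted p = 1.38e-07), alongside Tdgf1 (-8.30 ± 0.61), Zfp42 (-6.78 ± 0.43), Utf1 (-6.77 ± 0.43) and Dppa5a (-6.69 ± 0.78). The de novo DNA methylation genes Dnmt3l (-7.24 ± 0.66) and Dnmt3b (-5.18 ± 0.77) fell too. Among retinoic acid response and Hox genes 26 of 27 measured members rose and 1 fell. Their median was 5.73 (camera adjusted p = 3.42e-12, or 0.0657 with an estimated correlation). The largest rise was that of Cyp26b1, which degrades retinoic acid, to 1150 ± 12.7 CPM against 0.225 ± 0.031 (9.88 ± 0.49, adjusted p = 2.98e-12), and Rarb (7.16 ± 0.11) and Cyp26a1 (6.93 ± 0.49) rose with it. Of neural progenitor genes 16 of 18 measured members rose and 0 fell, led by the Notch effector Hes5 (7.61 ± 0.33), the radial glia gene Fabp7 (7.55 ± 0.30) and Irx3 (5.97 ± 0.15). Their median was 2.90 (camera adjusted p = 1.48e-05, or 0.52 with an estimated correlation). Of pan-neuronal genes 30 of 34 measured members rose and 1 fell, among them Celf3 (6.73 ± 0.15), Dcx (6.60 ± 0.12) and Myt1l (5.50 ± 0.13). Their median was 3.79 (camera adjusted p = 8.43e-13, or 0.398 with an estimated correlation). Interneuron and spinal cord transcription factors Lhx1 (7.67 ± 0.16), Dbx1 (7.55 ± 0.22), Lhx5 (6.13 ± 0.18) and Pax2 (5.81 ± 0.14) and the axon guidance receptor Robo3 (7.67 ± 0.20) rose, and for the GABAergic and glycinergic list the count was 10 up and 0 down of 12. Their median was 3.62 (camera adjusted p = 3.91e-05, or 0.348 with an estimated correlation). The glutamatergic list had 12 up and 0 down of 22, with Gria1 at 4.36 ± 0.11. Their median was 1.49 (camera adjusted p = 0.00113, or 0.52 with an estimated correlation). Cell cycle genes had 0 up and 22 down of 31. Their median was -1.25 (camera adjusted p = 6.57e-05, or 0.814 with an estimated correlation). Genes of the p53 response had 2 up and 15 down of 29. Their median was -1.09 (camera adjusted p = 0.00183, or 0.533 with an estimated correlation). Core spliceosome genes had 0 up and 4 down of 29, with Prpf8 (-1.49 ± 0.12), Prpf3 (-1.43 ± 0.10) and U2af1 (-1.10 ± 0.10). Their median was -0.71 (camera adjusted p = 1.15e-05, or 0.52 with an estimated correlation). Alternative splicing regulators had 17 up and 5 down of 45, with the neuronal microexon regulator Srrm4 at 4.61 ± 0.15 and Rbfox1 at 4.53 ± 0.14. Their median was 0.49 (camera adjusted p = 0.0314, or 0.708 with an estimated correlation). With the replicate block that camera adjusted p was 0.0561. Surface ectoderm genes had 0 up and 8 down of 11, with Krt17 (-4.69 ± 0.18) and Cdh1 (-4.25 ± 0.45). Their median was -2.23 (camera adjusted p = 0.0195, or 0.626 with an estimated correlation). Stress response genes had 1 up and 9 down of 19. Their median was -0.87 (camera adjusted p = 0.0285, or 0.626 with an estimated correlation).

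Between these stages limma called 3023 genes higher and 2542 lower in WT embryoid bodies, of 13938. Scaling to the total moved the median of all genes from 0.03 to 0.42 and the higher share of calls from 54.3% to 74.1%, against 47.9% with quantile scaling. The lists named above kept the sign of their median under all 3 scalings, the medians of interferon and endothelial genes moved from -0.13 and -0.05 to 0.33 and 0.23 with scaling to the total, and Puf60 itself changed by -0.04 as analysed, 0.44 with scaling to the total and 0.53 with quantile scaling. The remaining lists had camera adjusted p above 0.05: 3 up and 6 down of 10 for formative epiblast, 4 up and 1 down of 9 for cholinergic neurons, 6 up and 3 down of 14 for astrocytes, 3 up and 0 down of 9 for oligodendrocytes, 4 up and 6 down of 14 for mesoderm and 0 up and 2 down of 4 for skeletal muscle. The same held for endoderm (8 up and 4 down of 16), neural crest (4 up and 1 down of 10), fibroblasts (6 up and 4 down of 18), endothelium (2 up and 3 down of 12), forebrain and midbrain patterning (4 up and 1 down of 8) and immediate early genes (0 up and 5 down of 8). It held as well for the interferon response (2 up and 4 down of 15), hypoxia (3 up and 6 down of 19) and imprinted genes (7 up and 2 down of 16).

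From embryoid bodies to DIV7, neuronal genes rose further in WT. Of glutamatergic genes 15 of 22 measured members rose and 2 fell, with the receptor genes Grm5 (5.15 ± 0.15) and Grin1 (4.66 ± 0.22). Their median was 2.64 (camera adjusted p = 2.22e-06, or 0.289 with an estimated correlation). Of pan-neuronal genes 23 of 34 measured members rose and 1 fell, with the synaptic vesicle genes Syn2 (4.73 ± 0.14) and Syp (3.53 ± 0.13). Their median was 1.98 (camera adjusted p = 1.79e-08, or 0.52 with an estimated correlation). GABAergic genes had 8 up and 2 down of 12, with Calb2 (3.84 ± 0.20), Gad1 (3.71 ± 0.23) and Slc6a5 (3.38 ± 0.20). Their median was 2.26 (camera adjusted p = 0.0136, or 0.61 with an estimated correlation). The genes that rose most were Slc6a11 (6.28 ± 0.25), Tac1 (6.00 ± 0.28), Vsnl1 (5.81 ± 0.15) and Tnc (5.77 ± 0.30). Astrocyte genes had 9 up and 2 down of 14, with Gfap (5.71 ± 0.60), Aldh1l1 (5.03 ± 0.28) and Aldoc (4.64 ± 0.32). Their median was 1.41 (camera adjusted p = 0.0485, or 0.733 with an estimated correlation). Neural progenitor genes had 2 up and 13 down of 18, where Hes5 (-3.01 ± 0.33) and Irx3 (-2.93 ± 0.15) fell and Olig2 rose (3.40 ± 0.28). Their median was -1.62 (camera adjusted p = 0.00174, or 0.671 with an estimated correlation). Retinoic acid and Hox genes had 1 up and 18 down of 27, and Stra8 (-8.45 ± 0.31), Cyp26b1 (-8.09 ± 0.49), Crabp2 (-5.97 ± 0.50) and Hoxb9 (-6.17 ± 0.17) fell, the first of them to 0.236 ± 0.0306 CPM against 440 ± 117. Their median was -2.02 (camera adjusted p = 2.98e-05, or 0.283 with an estimated correlation). Cell cycle genes had 0 up and 31 down of 31, with Ccnb2 (-2.70 ± 0.19) and Aurkb (-2.62 ± 0.22). Their median was -2.10 (camera adjusted p = 7.48e-12, or 0.578 with an estimated correlation). Core spliceosome genes had 0 up and 2 down of 29, with Snrpb (-1.35 ± 0.11) and Dhx15 (-1.05 ± 0.10). Their median was -0.62 (camera adjusted p = 3.7e-07, or 0.456 with an estimated correlation). Hypoxia genes had 2 up and 9 down of 19, with the glucose transporter Slc2a1 at -4.65 ± 0.36. Their median was -0.85 (camera adjusted p = 0.0211, or 0.864 with an estimated correlation). Rbm38 fell at both steps (-1.09 ± 0.18, adjusted p = 1.15e-05, then -1.92 ± 0.18, adjusted p = 4.14e-09). Limma called 2451 genes higher and 1766 lower at DIV7, and scaling to the total moved the median of all genes from 0.02 to -0.11. Pluripotency genes stood at 2 up and 4 down of 26, with Lin28a (-3.16 ± 0.59) and Esrrb (2.63 ± 0.23) moving apart.

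At ESC each line was set against WT. In Puf60_pEx5_HOM, Naaa, a lysosomal amidase, rose to 49.6 ± 3.14 CPM against 10 ± 0.322 (2.20 ± 0.18, adjusted p = 5.79e-08). Lefty2, a Nodal inhibitor, rose to 152 ± 9.04 CPM against 35.1 ± 4.76 (2.09 ± 0.21, adjusted p = 5.03e-07, authors' FDR 0.174). Acta2, smooth muscle actin, fell to 2.14 ± 0.886 CPM against 49.5 ± 16.2 (-4.00 ± 0.47, adjusted p = 1.54e-05), and Tagln (-2.64 ± 0.51) and Col1a1 (-2.65 ± 0.68) with it (adjusted p from 0.00153 to 0.0122). T, the mesoderm transcription factor brachyury, fell to 3.06 ± 0.206 CPM against 21 ± 6.75 (-2.41 ± 0.17, adjusted p = 6.83e-09), and the simple epithelial keratins Krt8 (-2.16 ± 0.46) and Krt18 (-2.14 ± 0.47) fell. Of imprinted genes 0 of 16 measured members rose and 9 fell. Their median was -1.17 (camera adjusted p = 2.13e-07, or 0.0827 with an estimated correlation). Of naive pluripotency genes 1 of 26 measured members rose and 0 fell. Their median was 0.51 (camera adjusted p = 0.000751, or 0.803 with an estimated correlation). Of fibroblast and matrix genes 0 of 18 measured members rose and 5 fell. Their median was -0.62, with 0 up and 6 down adjusted over the list alone (camera adjusted p = 0.00167, or 0.8 with an estimated correlation). Formative epiblast genes had 0 up and 1 down of 10, with Cdh2 at -1.06 ± 0.10. Their median was -0.52 (camera adjusted p = 0.0188, or 0.51 with an estimated correlation). The intraflagellar transport gene Ift20 fell to 7.19 ± 0.264 CPM against 41.8 ± 0.378 (-2.39 ± 0.11, adjusted p = 8.79e-12), and it fell again at EB8 (-1.79 ± 0.11, adjusted p = 3.02e-09) and DIV7 (-1.52 ± 0.11, adjusted p = 2.53e-08). Limma called 135 genes higher and 209 lower at ESC (39.2% higher, or 25.8% with scaling to the total). In the authors' table Mapt (1.16), Gad1 (1.48) and Grin1 (1.86) rose and Gria3 (-1.63) fell.

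The other lines differed little from WT at ESC by the same test. In Puf60_mEx5_HOM 2 genes rose and 9 fell, of which 4 are Y-linked, and with the replicate letters as a block 6 rose and 11 fell. The imprinted gene Mest fell there (-1.86 ± 0.17, adjusted p = 1.25e-06, 52.7 ± 5.99 CPM against 193 ± 0.717). Of imprinted genes 0 of 16 measured members rose and 4 fell. Their median was -0.06, with 0 up and 6 down adjusted over the list alone (camera adjusted p = 0.0514, or 0.522 with an estimated correlation). Core spliceosome genes had 0 up and 0 down of 29. Their median was -0.10 (camera adjusted p = 0.000192, or 0.547 with an estimated correlation). In Puf60_pEx5_HET 3 genes rose, all imprinted noncoding RNAs of the Dlk1-Meg3 cluster: Meg3 (2.62 ± 0.36), Rian (2.25 ± 0.25) and Mirg (1.98 ± 0.23) (adjusted p from 0.000139 to 0.00297). In the authors' deposited table they changed by 2.79, 2.2 and 2.29, with an FDR of 0.696, 0.616 and 0.616. The other two called genes fell, among them Cdkn1c (-1.42 ± 0.20). In Rbm38KO 5 genes fell, Rbm38 and 4 imprinted genes, including Meg3 (-2.20 ± 0.36), Rian (-2.18 ± 0.25) and Mirg (-2.04 ± 0.23). Meg3, Rian and Mirg are neighbouring transcripts, and reads of 1 transcription unit were not separated, so they count as 1 observation. Leaving out replicate A of WT lowered the Puf60_pEx5_HET count from 5 to 2, and leaving out replicate A of Rbm38KO lowered that line's count from 5 to 3.

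When the 2 homozygous lines were set against each other at ESC, Acta2 (5.21 ± 0.47), Col1a1 (3.89 ± 0.68), Col1a2 (3.58 ± 0.64) and Actc1 (3.17 ± 0.30) were higher in Puf60_mEx5_HOM (adjusted p from 4.6e-07 to 0.000849). Of fibroblast and matrix genes 8 of 18 measured members rose and 0 fell. Their median was 1.07, with 9 up and 0 down adjusted over the list alone (camera adjusted p = 1.45e-05, or 0.626 with an estimated correlation). Of imprinted genes 5 of 16 measured members rose and 0 fell, with H19 (2.92 ± 0.39) and Igf2 (2.52 ± 0.45). Their median was 0.47 (camera adjusted p = 0.00145, or 0.285 with an estimated correlation). Lefty2 was lower (-2.27 ± 0.21), T was higher (1.92 ± 0.17), and naive pluripotency genes had 0 up and 1 down of 26. Their median was -0.56 (camera adjusted p = 0.000711, or 0.802 with an estimated correlation). Limma called 222 genes higher and 122 lower in Puf60_mEx5_HOM, or 64.5% higher, against 80.9% with scaling to the total, which moved the median of all genes to 0.10.

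In embryoid bodies some neuronal genes moved in opposite directions in the 2 homozygous lines. In Puf60_mEx5_HOM the neuropeptide gene Sst rose to 116 ± 13 CPM against 35.6 ± 5.3 (1.68 ± 0.17, adjusted p = 3.03e-06), and in Puf60_pEx5_HOM it fell to 7.53 ± 1.07 CPM against 35.6 ± 5.3 (-2.10 ± 0.17, adjusted p = 1.36e-07). The neuronal transcription factor Myt1l rose by 1.14 ± 0.13 in the former (adjusted p = 8.08e-06) and changed by -1.55 ± 0.13 in the latter (adjusted p = 1.36e-07). The tau gene Mapt did the same (1.02 ± 0.15, adjusted p = 0.000118, and -1.44 ± 0.15, adjusted p = 2.37e-06), as did the neuronal splicing factor Rbfox3 (1.02 ± 0.19, adjusted p = 0.000846, and -1.15 ± 0.19, adjusted p = 0.000252). Of pan-neuronal genes in Puf60_mEx5_HOM 4 of 34 measured members rose and 0 fell. Their median was 0.63 (camera adjusted p = 2.64e-15, or 0.293 with an estimated correlation). In Puf60_pEx5_HOM, of the same genes 0 of 34 measured members rose and 5 fell. Their median was -0.65 (camera adjusted p = 8.7e-23, or 0.258 with an estimated correlation). Among all 13938 genes, 77 were called in opposite directions in these lines, where independent lists of these sizes would share 2.5, and 72 of the 77 were higher in Puf60_mEx5_HOM. Without replicate B or A of Puf60_mEx5_HOM they were 59 or 97. The fold changes of both lines correlated across genes at r = -0.591 (covariance -0.0711), whereas 20 simulations of unchanged groups against the same WT libraries gave r = 0.498 (covariance 0.0137). Genes are not independent replicates, and shared controls push such values upward, not downward.

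**Figure D2:**
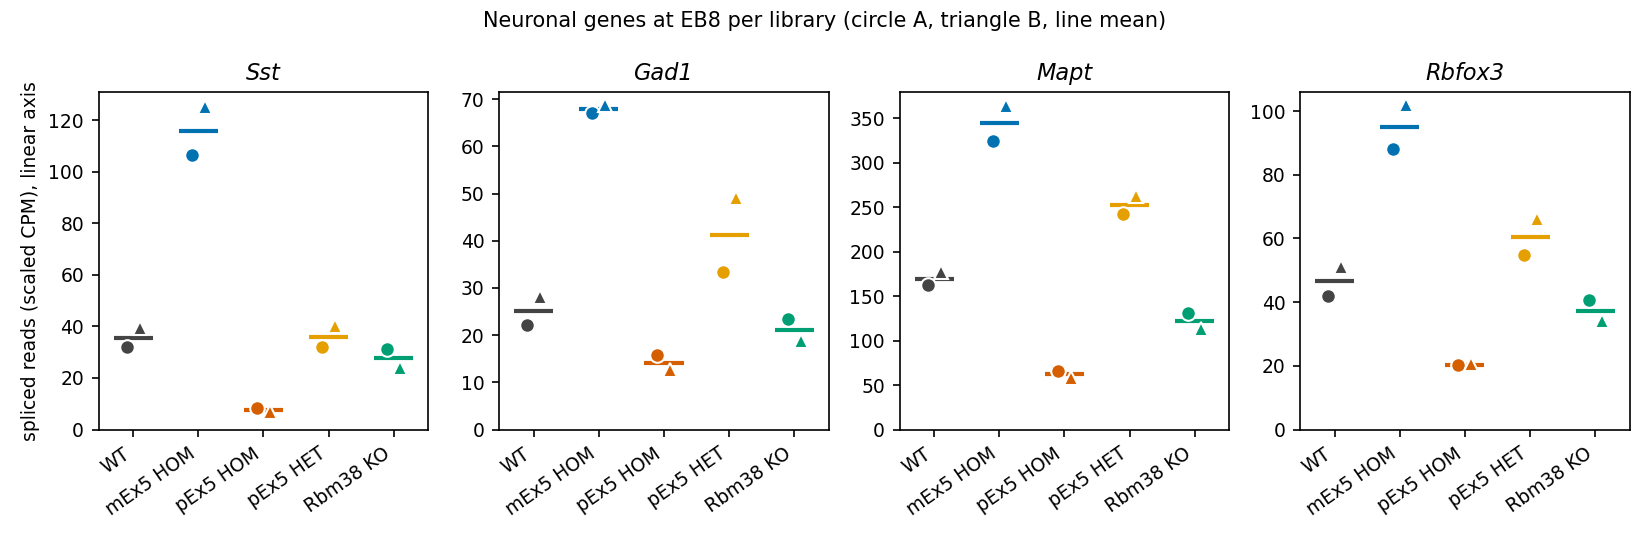
Normalised spliced read counts (CPM, y axis) of Sst, Gad1, Mapt and Rbfox3 in the 10 EB8 libraries by genotype, with circles for replicate A, triangles for replicate B and lines for the mean. For all 4 genes both Puf60_mEx5_HOM libraries lie above both WT libraries.

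In Puf60_mEx5_HOM embryoid bodies GABAergic genes had 5 up and 0 down of 12, with Npy (1.61 ± 0.21) and Gad1 (1.41 ± 0.23). Their median was 0.84 (camera adjusted p = 1.25e-07, or 0.27 with an estimated correlation). Glutamatergic genes had 4 up and 1 down of 22, where Grin1 (1.24 ± 0.22) and Neurod6 (1.09 ± 0.15) rose and Camk2a fell (-1.16 ± 0.20). Their median was 0.68 (camera adjusted p = 1.01e-07, or 0.283 with an estimated correlation). Endoderm genes had 1 up and 6 down of 16, including Gata4 (-1.23 ± 0.36), Krt18 (-1.89 ± 0.47) and Krt8 (-1.70 ± 0.46). Their median was -0.91, with 1 up and 7 down adjusted over the list alone (camera adjusted p = 0.000221, or 0.533 with an estimated correlation). Hypoxia genes had 3 up and 0 down of 19, with Pfkp (1.07 ± 0.34). Their median was 0.52 (camera adjusted p = 0.0125, or 0.854 with an estimated correlation). Cell cycle genes had 0 up and 0 down of 31. Their median was -0.74 (camera adjusted p = 5.89e-17, or 0.52 with an estimated correlation). The imprinted adaptor gene Grb10 fell (-3.13 ± 0.22, adjusted p = 5.14e-09). It also fell in Puf60_pEx5_HET and Rbm38KO against the same WT libraries, so the edit need not be the cause. Limma called 164 genes higher and 65 lower, and leaving out replicate B of WT raised the total. Cholinergic genes, core spliceosome genes and interferon genes had no called member. Their medians were -0.33, -0.19 and -0.45 (camera adjusted p = 0.0285, 1.8e-05 and 0.00317, or 0.285, 0.52 and 0.626 with an estimated correlation).

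In Puf60_pEx5_HOM embryoid bodies, GABAergic genes had 0 up and 3 down of 12, with the vesicular transporter Slc32a1 at -1.10 ± 0.17. Their median was -0.61 (camera adjusted p = 1.1e-05, or 0.289 with an estimated correlation). Glutamatergic genes had 0 up and 2 down of 22, with Shank1 (-1.61 ± 0.18) and Slc17a6 (-1.24 ± 0.22). Their median was -0.30 (camera adjusted p = 1.59e-05, or 0.373 with an estimated correlation). Cholinergic genes had 0 up and 1 down of 9, with Prph at -1.43 ± 0.32. Their median was -0.55 (camera adjusted p = 0.000981, or 0.109 with an estimated correlation). The neuronal splicing regulators Rbfox1 (-1.45 ± 0.14) and Celf5 (-1.34 ± 0.12) fell (adjusted p from 1.5e-07 to 5.53e-07). Matrix genes had 0 up and 3 down of 18, led by Col3a1 at 13.1 ± 6.54 CPM against 95.4 ± 50.1 (-2.75 ± 0.62, adjusted p = 0.00846). Their median was -0.54 (camera adjusted p = 0.0468, or 0.864 with an estimated correlation). Krt8 rose (1.65 ± 0.46, adjusted p = 0.0279), and surface ectoderm genes had 1 up and 0 down of 11. Their median was 0.66, with 3 up and 0 down adjusted over the list alone (camera adjusted p = 0.00239, or 0.52 with an estimated correlation). Cell cycle genes, core spliceosome genes and p53 targets had no called member. Their medians were 0.30, 0.12 and 0.23 (camera adjusted p = 1.06e-05, 0.000301 and 0.00174, or 0.802, 0.569 and 0.533 with an estimated correlation). Limma called 30 genes higher and 201 lower.

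The 500 genes that rose most from ESC to DIV7 in the other lines, a list made from these samples and so not independent evidence of direction, followed the same split. In Puf60_mEx5_HOM 84 up and 0 down of 500 passed the test. Their median was 0.73, with 85 up and 1 down adjusted over the list alone (camera adjusted p = 1.96e-63, or 0.164 with an estimated correlation). In Puf60_pEx5_HOM the counts were 0 up and 117 down of 500. Their median was -0.71, with 1 up and 118 down adjusted over the list alone (camera adjusted p = 3.12e-78, or 0.105 with an estimated correlation). Of the 500 that fell most, the counts were 0 up and 14 down of 500 in Puf60_mEx5_HOM. Their median was -0.46, with 0 up and 15 down adjusted over the list alone (camera adjusted p = 5.53e-23, or 0.533 with an estimated correlation). They were 7 up and 0 down of 500 in Puf60_pEx5_HOM. Their median was 0.29 (camera adjusted p = 1.16e-12, or 0.721 with an estimated correlation).

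In Puf60_pEx5_HET embryoid bodies, Meg3 (2.42 ± 0.36), Rian (2.03 ± 0.25) and Mirg (1.88 ± 0.23) rose and Dlk1 (-3.78 ± 0.29), Grb10 (-3.43 ± 0.22) and Igf2 (-2.54 ± 0.45) fell (adjusted p from 6.28e-09 to 0.0214), Dlk1 to 18 ± 5.61 CPM against 255 ± 25.1. The authors' deposited table gave an FDR of 0.398, 0.308 and 0.24 for Meg3, Rian and Mirg. For Dlk1, Grb10 and Igf2 its FDR was 6.92e-10, 2.6e-65 and 0.00702. Of imprinted genes 3 of 16 measured members rose and 3 fell, with a mean of -0.03 where the median is above 0. Their median was 0.28, with 4 up and 3 down adjusted over the list alone (camera adjusted p = 0.218, or 0.748 with an estimated correlation). Pan-neuronal genes had 0 up and 0 down of 34. Their median was 0.38 (camera adjusted p = 1.06e-16, or 0.285 with an estimated correlation). Endoderm genes had 0 up and 1 down of 16. Their median was -0.75, with 0 up and 3 down adjusted over the list alone (camera adjusted p = 2.22e-06, or 0.456 with an estimated correlation). Limma called 3 genes higher and 13 lower, 16 in all, a count that moved when a library was left out. In Rbm38KO embryoid bodies the imprinted zinc finger gene Peg3 rose (1.10 ± 0.15, adjusted p = 0.00055) and Grb10 (-4.01 ± 0.22), Meg3 (-3.22 ± 0.36), Rian (-2.23 ± 0.25) and Mirg (-1.98 ± 0.23) fell (adjusted p from 1.5e-10 to 0.000159). Pan-neuronal genes had 0 up and 0 down of 34. Their median was -0.34 (camera adjusted p = 2e-20, or 0.283 with an estimated correlation). Limma called 1 gene higher and 5 lower, with 9 in all when replicate A of Rbm38KO was left out.

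Set against each other in embryoid bodies, the homozygous lines differed in 968 genes higher and 425 lower in Puf60_mEx5_HOM by limma, or 69.5% higher, against 59.5% with quantile scaling. Of pan-neuronal genes 27 of 34 measured members rose and 0 fell, with Sst (3.78 ± 0.17), Kcnq3 (3.66 ± 0.18) and Sez6 (3.61 ± 0.17) among the largest differences of the comparison. Their median was 1.16 (camera adjusted p = 3.2e-18, or 0.285 with an estimated correlation). Glutamatergic genes had 12 up and 1 down of 22. Their median was 1.14 (camera adjusted p = 8.66e-07, or 0.285 with an estimated correlation). GABAergic genes had 7 up and 0 down of 12. Their median was 1.45 (camera adjusted p = 1.12e-06, or 0.285 with an estimated correlation). Of cell cycle genes 0 of 31 measured members rose and 22 fell, with the nucleotide and replication genes Tyms (-1.35 ± 0.27), Rrm2 (-1.32 ± 0.20) and Mcm3 (-1.22 ± 0.23). Their median was -1.06 (camera adjusted p = 2.88e-13, or 0.533 with an estimated correlation). Keratins and E-cadherin were lower (Krt8 (-3.35 ± 0.46), Krt18 (-3.34 ± 0.47) and Cdh1 (-2.24 ± 0.45)), and surface ectoderm genes had 1 up and 5 down of 11. Their median was -0.89 (camera adjusted p = 0.0136, or 0.607 with an estimated correlation). Matrix genes had 9 up and 0 down of 18, with Col3a1 at 3.94 ± 0.62. Their median was 1.00 (camera adjusted p = 0.019, or 0.843 with an estimated correlation). Alternative splicing regulators had 13 up and 2 down of 45, with Celf5 (2.17 ± 0.12) and Rbfox3 (2.17 ± 0.19) higher and a mean of 0.28 above a median below 0. Their median was -0.02 (camera adjusted p = 0.266, or 0.864 with an estimated correlation).

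At DIV7, pluripotency genes stood higher in Puf60_pEx5_HOM than in WT: 17 of 26 measured members rose and 1 fell. Their median was 1.62, with 18 up and 1 down adjusted over the list alone (camera adjusted p = 2.71e-08, or 0.547 with an estimated correlation). Pou5f1 was at 56.8 ± 26.5 CPM against 6.11 ± 3.74 (3.05 ± 0.84, adjusted p = 0.0226) and the stem cell gene Dppa5a at 58 ± 8.96 CPM against 6.79 ± 2.78 (2.96 ± 0.78, adjusted p = 0.0181). Of astrocyte genes 0 of 14 measured members rose and 4 fell, with the intermediate filament gene Gfap at 7.98 ± 0.898 CPM against 131 ± 59.8 (-3.80 ± 0.60, adjusted p = 0.000534). Their median was -0.63 (camera adjusted p = 1.12e-06, or 0.285 with an estimated correlation). Of endoderm genes 0 of 16 measured members rose and 7 fell, with the transcription factors Gata4 (-3.19 ± 0.36), Gata6 (-2.45 ± 0.34) and Sox17 (-2.65 ± 0.41). Their median was -0.79 (camera adjusted p = 7.15e-09, or 0.285 with an estimated correlation). Matrix genes had 0 up and 6 down of 18, with Sparc (-2.35 ± 0.30) and Dcn (-2.06 ± 0.47). Their median was -1.08, with 0 up and 8 down adjusted over the list alone (camera adjusted p = 4.94e-06, or 0.607 with an estimated correlation). Oligodendrocyte genes had 0 up and 3 down of 9, with Pdgfra (-2.48 ± 0.49) and Sox10 (-1.36 ± 0.37). Their median was -0.72 (camera adjusted p = 0.000515, or 0.52 with an estimated correlation). The activity-dependent genes Npas4 (3.01 ± 0.62), Nr4a1 (2.73 ± 0.45) and Fos (2.69 ± 0.73) rose, and their list had 3 up and 0 down of 8. Their median was 1.29, with 4 up and 0 down adjusted over the list alone (camera adjusted p = 0.0035, or 0.54 with an estimated correlation). The stomach and gut genes Aqp8 (-5.76 ± 0.53), Gkn2 (-4.15 ± 0.40) and Gkn1 (-3.83 ± 0.33) fell (adjusted p from 1.01e-06 to 3.01e-06), and the VEGF receptor gene Flt1 fell (-2.85 ± 0.42). Habp2 and Nepn had 0 reads and were at least 111- and 39.6-fold lower. Neural progenitor genes had 0 up and 2 down of 18, with Olig2 (-1.17 ± 0.28) and Hes5 (-1.13 ± 0.33). Their median was -0.29 (camera adjusted p = 0.0226, or 0.802 with an estimated correlation). Interferon genes had 0 up and 2 down of 15. Their median was -0.42 (camera adjusted p = 0.000173, or 0.52 with an estimated correlation). Core spliceosome genes had 0 up and 0 down of 29. Their median was 0.19 (camera adjusted p = 0.000221, or 0.551 with an estimated correlation). Pan-neuronal genes had 0 up and 0 down of 34, and the 500 genes that fall most from ESC to DIV7 in the other lines, chosen on these samples, had 69 up and 3 down of 500. Their median was 0.37, with 74 up and 5 down adjusted over the list alone (camera adjusted p = 3.03e-09, or 0.802 with an estimated correlation). Limma called 121 genes higher and 237 lower, 358 in all, or 113 with the DIV7 libraries alone, and leaving out a WT library moved this count.

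**Figure D3:**
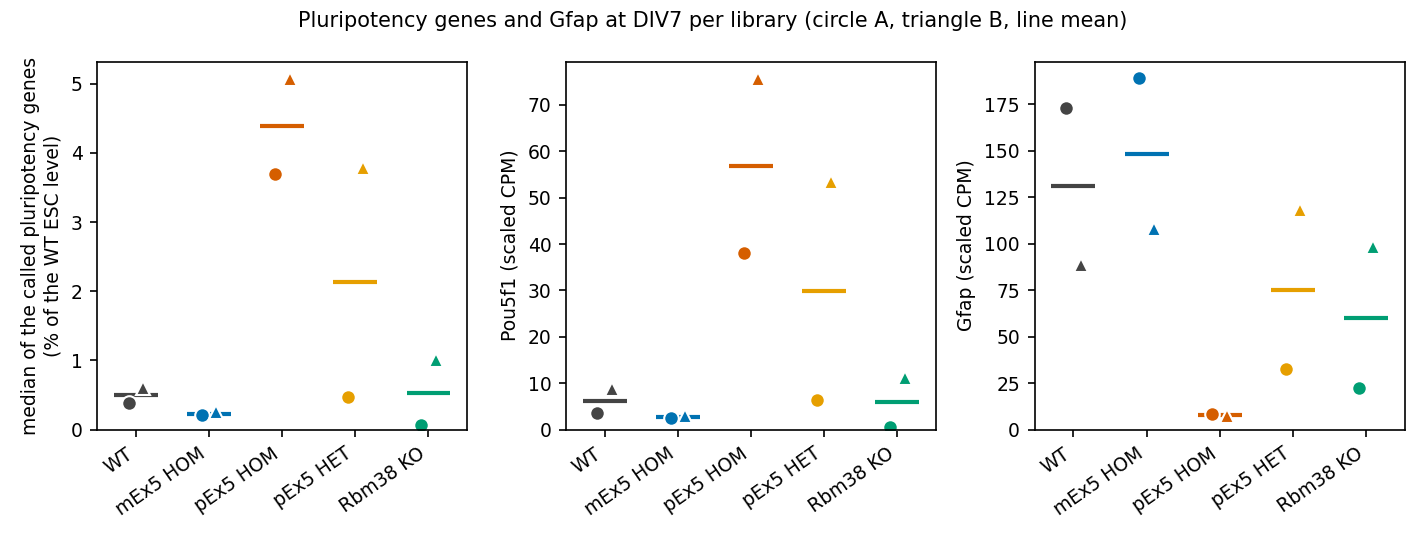
Median of the called pluripotency genes (% of the WT ESC level, y axis) and Pou5f1 and Gfap (CPM, y axes) in the 10 DIV7 libraries by genotype, with circles for replicate A, triangles for replicate B and lines for the mean. Pou5f1 is at 38.1 and 75.6 CPM in the Puf60_pEx5_HOM libraries, 3.46 and 8.76 in WT, and 6.33 and 53.4 in Puf60_pEx5_HET.

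In Puf60_pEx5_HET at DIV7 endoderm genes had 0 up and 7 down of 16, with Gata4 (-1.81 ± 0.36), Gata6 (-1.76 ± 0.34) and Dab2 (-1.98 ± 0.33), where Gata4 was at 15.9 and 6.14 CPM in the WT libraries, 1.47 and 2.96 in this line and 1.46 and 5.81 in Rbm38KO. Their median was -1.02, with 0 up and 8 down adjusted over the list alone (camera adjusted p = 1.1e-13, or 0.197 with an estimated correlation). Flt1 (-2.11 ± 0.42), Cyp26a1 (-2.44 ± 0.49), Aqp8 (-2.88 ± 0.53) and Ctsh (-2.70 ± 0.36) fell too. Dlk1 fell (-3.03 ± 0.29, adjusted p = 8.48e-06) and Rian (1.92 ± 0.25), Mirg (1.80 ± 0.23) and Meg3 (1.60 ± 0.36) rose. In the authors' deposited table the FDR was 4.01e-08 for Dlk1 and 0.339, 0.189 and 0.869 for Rian, Mirg and Meg3. Of pluripotency genes 0 rose and 1 fell, Klf4 (-1.63 ± 0.23, adjusted p = 0.000508), below a median of the other sign, with the libraries apart at 0.01 and 1.62. Their median was 0.72 (camera adjusted p = 0.00382, or 0.83 with an estimated correlation). In Rbm38KO at DIV7 endoderm genes had 0 up and 3 down of 16, with Dab2 (-1.77 ± 0.33), and by library the list stood at -1.52 and -0.74 against 0.42 and -0.42 in WT. Their median was -1.26, with 0 up and 10 down adjusted over the list alone (camera adjusted p = 4.77e-19, or 0.105 with an estimated correlation). Endothelial genes had 0 up and 2 down of 12, with Flt1 (-2.02 ± 0.42) and Tek (-1.27 ± 0.23). Their median was -0.12 (camera adjusted p = 0.00684, or 0.533 with an estimated correlation). Fibroblast and matrix genes had 0 up and 0 down of 18. Their median was -0.57 (camera adjusted p = 3.64e-07, or 0.533 with an estimated correlation). Meg3 fell to 21.4 ± 3.95 CPM against 361 ± 2.76 (-4.02 ± 0.36, adjusted p = 4.82e-06) with Rian (-3.08 ± 0.25) and Mirg (-2.42 ± 0.23), and the sensory neuron transcription factor gene Pou4f1 was the 1 gene that rose (1.16 ± 0.18, adjusted p = 0.0016). Limma called 6 genes higher and 74 lower in Puf60_pEx5_HET and 1 higher and 41 lower in Rbm38KO, and with the DIV7 libraries fitted alone 5 in each line, so most of these calls rest on the spread pooled over stages. Leaving out a library moved the counts of both lines as well. Of the genes lower in Puf60_pEx5_HET, 65 were also lower in Puf60_pEx5_HOM, where independent lists would share 1.26 (r = 0.769 and covariance 0.0809). Simulated unchanged groups gave 0.5 and 0.0136 and shared 0 in every pair of lines, which is no benchmark. The 65 became 1 with the DIV7 libraries fitted alone, 7 without replicate A of WT and 203 without replicate B of WT. Rbm38KO shared 31 lower genes with Puf60_pEx5_HOM and 30 with Puf60_pEx5_HET (0.697 and 0.218 for independent lists). Their r was 0.542 and 0.604 against 0.499 and 0.495 simulated, with covariances of 0.0501 and 0.0365 against 0.0137 and 0.0135. These overlaps became 0 and 1 with the DIV7 libraries alone and moved with single libraries left out. Puf60_pEx5_HET and Rbm38KO also deviated together by replicate letter (correlation 0.603).

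In Puf60_mEx5_HOM at DIV7 the imprinted Notch-family ligand gene Dlk1 rose to 240 ± 142 CPM against 32.8 ± 6.85 (2.71 ± 0.29, adjusted p = 3.2e-05), while Meg3 (-2.10 ± 0.36) and Mirg (-1.46 ± 0.23) of the same cluster fell. The progenitor transcription factor genes Pax6 (-1.04 ± 0.18) and Neurog2 (-1.03 ± 0.23) fell (adjusted p from 0.00367 to 0.0282), and neural progenitor genes had 0 up and 2 down of 18. Their median was -0.56 (camera adjusted p = 2.07e-06, or 0.52 with an estimated correlation). GABAergic genes had 1 up and 0 down of 12. Their median was 0.31 (camera adjusted p = 0.0421, or 0.708 with an estimated correlation). Glutamatergic genes had 0 up and 0 down of 22. Their median was 0.27 (camera adjusted p = 0.000134, or 0.478 with an estimated correlation). The matrix genes Thbs2 (1.66 ± 0.37) and Ogn (1.44 ± 0.32) rose, and fibroblast genes had 0 up and 0 down of 18. Their median was 0.68, with 1 up and 0 down adjusted over the list alone (camera adjusted p = 0.00052, or 0.748 with an estimated correlation). Cell cycle genes had 0 up and 0 down of 31. Their median was -0.52 (camera adjusted p = 3.33e-14, or 0.533 with an estimated correlation). Endoderm genes had 0 up and 0 down of 16. Their median was -0.66, with 0 up and 2 down adjusted over the list alone (camera adjusted p = 0.000106, or 0.52 with an estimated correlation). In the authors' table the FDR was 8.35e-06 for Dlk1 and 0.0927 to 0.737 for Pax6, Neurog2, Thbs2, Ogn, Meg3 and Mirg. Limma called 25 genes higher and 30 lower, 55 in all, or 10 with the DIV7 libraries alone. Leaving out a WT library moved this count. Against Puf60_pEx5_HOM, 214 genes were higher and 174 lower in Puf60_mEx5_HOM (232 in all with the DIV7 libraries alone). Pluripotency genes had 1 up and 18 down of 26, with Pou5f1 (-3.89 ± 0.84) and Dppa5a (-4.07 ± 0.78). Their median was -1.97 (camera adjusted p = 6.71e-11, or 0.52 with an estimated correlation). Matrix genes had 12 up and 0 down of 18, with Col1a1 (3.01 ± 0.68) and Col3a1 (2.69 ± 0.62). Their median was 1.84 (camera adjusted p = 2.76e-10, or 0.493 with an estimated correlation). Gfap was at 149 ± 57.4 CPM against 7.98 ± 0.898 (4.01 ± 0.60, adjusted p = 0.000255), with astrocyte genes at 4 up and 0 down of 14. Their median was 0.50 (camera adjusted p = 0.000711, or 0.52 with an estimated correlation). The activity genes Npas4 (-2.41 ± 0.62) and Fos (-2.35 ± 0.73) were lower, with their list at 0 up and 4 down of 8. Their median was -1.27 (camera adjusted p = 0.00475, or 0.551 with an estimated correlation). Cell cycle genes had 0 up and 4 down of 31. Their median was -0.69 (camera adjusted p = 4.22e-10, or 0.626 with an estimated correlation).

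Effects of an edit were compared between stages, but a gene silent at ESC differs only by its later change. In Puf60_pEx5_HOM the change from WT differed from that at ESC for 1665 genes at EB8 and 1567 at DIV7 by limma's interaction test, which has no fold minimum, so these numbers do not compare with the counts of called genes. In Puf60_mEx5_HOM the numbers were 652 and 14, in Puf60_pEx5_HET 2 and 14, and in Rbm38KO 1 and 4. With the replicate letters as a block they were 2428 for Puf60_pEx5_HOM at DIV7, 1124 and 48, 4 and 22, and 7 and 13. They depended on single libraries, with ranges given below. Called in the same direction at all 3 stages were 1 higher and 8 lower genes in Puf60_mEx5_HOM, 0 and 2 in Puf60_pEx5_HOM, 3 and 0 in Puf60_pEx5_HET and 0 and 4 in Rbm38KO.

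**Figure D4:**
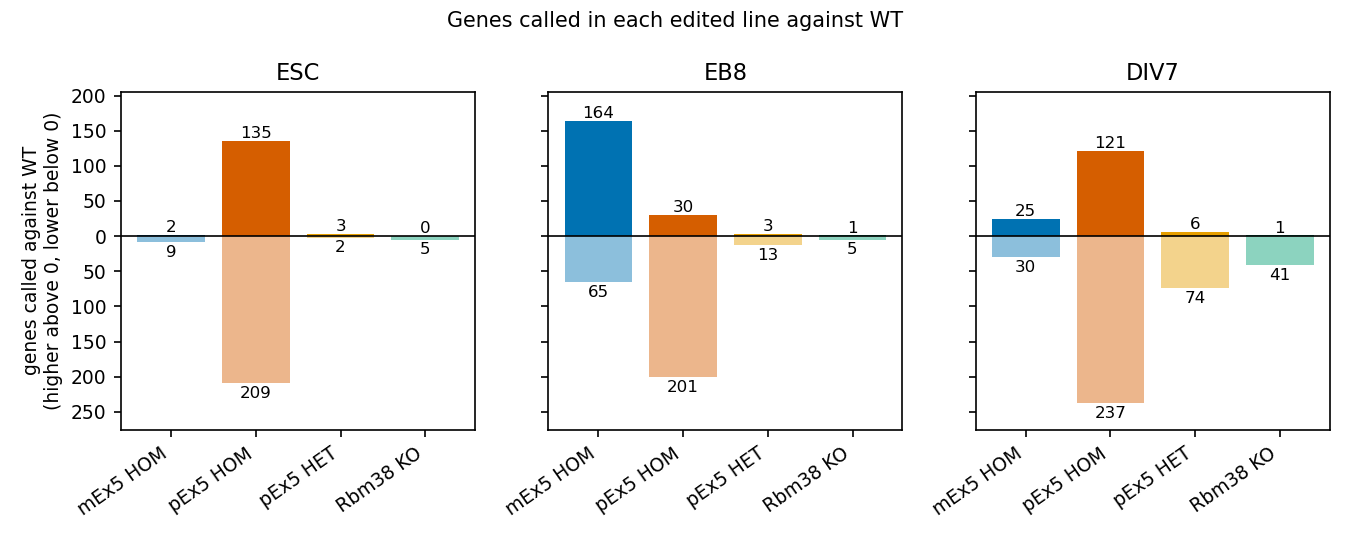
Number of genes called higher and lower than WT by limma (y axis) in each edited line at each stage. Puf60_pEx5_HOM has 135 higher and 209 lower at ESC, and Puf60_mEx5_HOM 164 higher and 65 lower at EB8.

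Splicing of WT cells was compared between stages. From ESC to EB8, a 9-nt microexon of Fry rose from 6.1 ± 5.11% to 90.8 ± 4.72% (adjusted p = 9.04e-05 in the read-weighted limma fit) and an exon of the microtubule gene Map2 fell from 96.3 ± 0.332% to 2.35 ± 0.255% (adjusted p = 3.29e-06). A 24-nt microexon of the DNA demethylase gene Tet2 fell from 95.5 ± 0.573% to 9.05 ± 2.66% (adjusted p = 4.97e-06). From EB8 to DIV7, a 27-nt microexon of Baz2b rose from 21.9 ± 0.665% to 98.2 ± 0.17% (adjusted p = 7.87e-07) and an exon of the neuronal splicing factor gene Nova1 fell from 90.9 ± 2.35% to 10 ± 0.17% (adjusted p = 4.44e-07). The planned fit called 2488 and 2549 events and the read-weighted fit 2670 and 3044, of which 1657 and 1974 had higher inclusion at the later stage. In the read-weighted fit 57.7% of 376 tested microexons changed from ESC to EB8, against 21.2% of longer cassette exons (odds ratio 5.07, Fisher's exact test adjusted p = 1.36e-48), and 61.4% against 25.8% from EB8 to DIV7 (odds ratio 4.58, Fisher's exact test adjusted p = 8.37e-44). The planned fit's counts fell to 1254 and 717 at lowest when 1 library was left out.

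Among edited lines, Puf60_pEx5_HOM had the most events called. An exon of the neuregulin gene Nrg1 fell from 100 ± 0% to 47.7 ± 7.93% at ESC (adjusted p = 0.00262 in the read-weighted limma fit). An exon of Slc35b3, a transporter gene for the sulfate donor PAPS, fell from 62.4 ± 11.5% to 12.3 ± 2.4% at EB8 (adjusted p = 0.000715) and from 81.5 ± 2.11% to 30.8 ± 15.3% at DIV7 (adjusted p = 0.0126). An exon of the interferon-inducible gene Ifi27 fell from 90.4 ± 0.714% to 27.6 ± 1.46% at EB8 (adjusted p = 0.000319, and adjusted p = 0.0368 in the planned fit). At DIV7 an exon of the lipase gene Daglb fell from 97.3 ± 2.45% to 55.4 ± 4.88% and 1 of Mical2 rose from 29.9 ± 15.5% to 73.8 ± 6.68% (adjusted p = 0.0421 and adjusted p = 0.0355). The read-weighted fit called 278, 561 and 279 events at ESC, EB8 and DIV7, and the planned fit 1, 36 and 0, with 27083 at unadjusted p below 0.05 for the last. The planned count of 36, Ifi27 included, was 0 without replicate A of WT. Without replicate B of Puf60_pEx5_HOM the read-weighted counts were 79 at ESC and 164 at EB8, and at DIV7 they ranged from 104 to 128 when 1 library was left out. Of the read-weighted calls, 43 rose and 55 fell at both ESC and EB8, where independent lists would share 1.6 and 1.38, and these comparisons share no library. Exon 5 of Puf60 is 1 of the 43.

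In Puf60_mEx5_HOM embryoid bodies, an exon of the axon guidance receptor gene Neo1 fell from 75.2 ± 1.53% to 44 ± 4.21% (adjusted p = 0.000936) and a 24-nt microexon of the guidance ligand gene Slit2 fell from 65 ± 0.417% to 32.7 ± 3.61% (adjusted p = 0.0488). A 9-nt microexon of Dtna rose from 41 ± 0.587% to 77.9 ± 2.98% (adjusted p = 0.0173). At DIV7 an exon of the synaptic adhesion gene Nlgn3 fell from 68 ± 2.03% to 39.5 ± 1.05% (adjusted p = 0.0056) and 1 of Asap2 from 34.2 ± 4.72% to 6.36 ± 0.177% (adjusted p = 0.00174). The read-weighted limma fit called 0, 74 and 17 events at ESC, EB8 and DIV7 and the planned fit 0, 1 and 0, with 2 at ESC in the former under the replicate block. At ESC 1140 events in the former and 13993 in the latter had an unadjusted p below 0.05, and at DIV7 17576 in the latter. The 13993 of 309671 events are under the chance share of 0.05. The read-weighted EB8 and DIV7 counts fell when 1 library was left out. Of the EB8 events, 23 were called in the opposite direction in Puf60_pEx5_HOM, where independent lists would share 0.88. Between the homozygous lines the read-weighted fit called 470, 1699 and 760 events and the planned fit 40 (1 with the replicate block), 941 and 25. At EB8 38.8% of 441 tested microexons differed between these lines against 14% of longer cassette exons (odds ratio 3.89, Fisher's exact test adjusted p = 2.42e-34), with odds ratios of 1.94 at ESC (adjusted p = 0.0358) and 0.82 at DIV7 (adjusted p = 0.788). In the planned fit Fisher's exact test gave odds ratios of 9.54 at EB8 (adjusted p = 8.17e-58), 2.08 at ESC and 0 at DIV7 (adjusted p = 1 and 1), and 10.1 and 8.49 between the WT stages (adjusted p = 1.93e-120 and 3.13e-102). Leaving out 1 library lowered the read-weighted counts to 212, 968 and 370 at lowest and the planned ones to 1, 94 and 2.

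In Puf60_pEx5_HET an exon of the ubiquitin ligase gene Fbxl20 fell from 92.7 ± 4.21% to 50.8 ± 10.5% at EB8 (adjusted p = 0.0193) and from 95.6 ± 0.354% to 46.7 ± 7.2% at DIV7 (adjusted p = 0.00894). A 149-nt exon of Mid1 fell from 91.2 ± 0.834% to 72.9 ± 1.73% at ESC (adjusted p = 0.00972), from 95.6 ± 0.983% to 81.9 ± 4.82% at EB8 (adjusted p = 0.0352) and from 93.7 ± 1.03% to 80.5 ± 0.403% at DIV7 (adjusted p = 0.049). The read-weighted limma fit called 5, 4 and 3 events in this line and 0, 1 and 0 in Rbm38KO, and the planned fit 0, 0 and 0 and 0, 5 and 0. At unadjusted p below 0.05 the planned fit had 14522, 24522 and 15737 events in the former line and 13951, 18091 and 13365 in Rbm38KO, and the read-weighted fit had 1003 at ESC and 1088 at DIV7 in Rbm38KO. Leaving out 1 library moved the read-weighted counts of both lines.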

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

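The tests of exon 5 inclusion, of differences between lines that do not follow exon 5, of Y chromosome loss, of X-linked genes, of mislabelled libraries and of 1 library alone were chosen only after the results were seen.

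In embryoid bodies the 77 genes called in opposite directions in the homozygous lines, 72 of them higher in Puf60_mEx5_HOM, moved by a median of -1.17 in that line and 1.36 in Puf60_pEx5_HOM, taken in the direction of the latter. Inclusion of exon 5 as the whole cause is argued against. Puf60_pEx5_HET, with inclusion above WT, had a median of -0.36 taken in the same direction (-0.33 and -0.38 by library, WT 0.05 and -0.05). A candidate explanation is that the lines stood at different points of 1 differentiation course: of genes lower in Puf60_mEx5_HOM than in Puf60_pEx5_HOM 85.6% fell from EB8 to DIV7 in WT, and of the higher ones 90.9% rose. Differences between lines that do not follow exon 5 stay open too. Rbm38KO, with WT-like inclusion, had a median of 0.45 (0.28 and 0.60 by library). The state of 2 edited alleles was not tested apart from these.

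Y-linked genes had no reads in Puf60_mEx5_HOM. Libraries of another line of the series under this label are argued against, since Puf60 expression of 0 of the 6 libraries lay within the range of the other lines, with gaps of 106, 41.1 and 62.6 CPM by stage against at most 16.1, 23.3 and 21.1 between replicates. A line with 2 X chromosomes is argued against by X-linked genes at ESC, with a median of -0.03, and Xist at 0.658 times the highest other line rests on 2 reads against 3 and adds little. Loss of the Y chromosome from the line may explain the pattern and stays open, since its test, a highest count of 0 for any Y-linked gene in these libraries, restates the pattern. A sample from outside the series and biological explanations were not tested.

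At DIV7, 17 called pluripotency genes were higher in Puf60_pEx5_HOM than in WT. A single library as the source is argued against. Both libraries lay above both of WT for 23 of all 26 measured list members, called or not, which may move together. The list medians by library were 1.31 and 1.7 against -0.09 and 0.09. Leftover undifferentiated cells may explain it. Of 43 other ESC-restricted genes 97.7% were higher, by a median 2.65% of the ESC level (list 2.54%). Choosing genes low in DIV7 WT favours this. Exon 5 inclusion and other differences between lines cannot be told apart, because Puf60_pEx5_HET had a median of 0.93 from libraries at 0.05 and 1.88, where WT had -0.18 and 0.18.

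Interaction tests found genes whose change from WT differed from ESC: 652 at EB8 and 14 at DIV7 in Puf60_mEx5_HOM, 1665 and 1567 in Puf60_pEx5_HOM, 2 and 14 in Puf60_pEx5_HET, and 1 and 4 in Rbm38KO. At DIV7 the differences of Gata4, Gfap, Gkn1, Gkn2 and Sox17 in Puf60_pEx5_HOM nearly equalled their change there, as for genes silent at ESC. So these need not be stage-dependent effects. Named-gene differences (log2) in Puf60_pEx5_HOM at EB8 were Acta2 4.12, Aqp8 -2.38, Cdh2 0.97, Celf5 -1.51, Gkn1 -2.18, Gkn2 -2.59, Ift20 0.6, Krt18 3.59, Krt8 3.81, Lefty2 -1.67, Mapt -2.49, Myt1l -1.61, Naaa -2.11, Rbfox1 -1.22, Rbfox3 -1.09, Shank1 -1.67, Slc17a6 -1.22, Slc32a1 -0.91, Sst -2.03, T 2.5 and Tagln 3.39. At DIV7 they were Acta2 3.73, Aqp8 -5.78, Cdh2 1.22, Gata4 -3.18, Gata6 -2.38, Gfap -3.81, Gkn1 -3.83, Gkn2 -4.15, Hes5 -1.61, Ift20 0.87, Krt18 2.13, Lefty2 -0.96 (low CPM, sign unsure), Mapt -1.04, Naaa -2.77, Npas4 3.03, Nr4a1 2.48, Pdgfra -2.47, Sox17 -2.65, Sparc -2.08, Sst 0.88, T 2.65 and Tagln 2.91. In Puf60_mEx5_HOM they were Gad1 1.23, Grb10 -1.96, Mapt 0.93, Mid1 2.2, Myt1l 1.11, Neurod6 1.09, Npy 1.58, Rbfox3 1.11 and Sst 1.75 at EB8 and Dlk1 2.89 at DIV7. In Puf60_pEx5_HET they were Dlk1 -4.3 and Grb10 -1.93 at EB8 and Dlk1 -3.55 and Grb10 1.69 at DIV7, and in Rbm38KO Grb10 -2.4 at EB8.

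A signal in data outside the tests is that the authors' deposited table of mean PSI calls 41281 events for Puf60_pEx5_HOM against WT at EB8, against 2617 to 6690 in its other comparisons. In the authors' deposited table the median difference of the former is 1.65 points and 5.19% reach 10 points.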

How the results depend on the processing

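Of the tests here, scaling to the total, voom weights, the authors' deposited table, the read-weighted fit with its alternatives, the block for gene lists and the events with variable PSI were chosen only after results were seen. Depth limits the results as follows: genes under 1 CPM and events under 10 reads were not tested, and most simulated splicing differences of 15 points were missed. The edgeR and DESeq2 alternatives planned for deposited gene counts were not run on spliced reads. Each series below gives Puf60_mEx5_HOM, Puf60_pEx5_HOM, Puf60_pEx5_HET and Rbm38KO against WT, then the homozygous lines against each other.

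All 17 limma counts of called genes stayed within 1.5 times their value with quantile scaling, scaling to the total, no filter and no trend. Without the fold minimum, which lets smaller changes pass, 17 of 17 moved: 41, 2457, 10, 16 and 2717 at ESC, 2531, 1426, 45, 15 and 6092 at EB8, 193, 2202, 169, 72 and 2642 at DIV7 and 10955 and 9971 between WT stages. A pseudocount of 0.1 moved 9 of 17: Puf60_mEx5_HOM 22 at ESC and 515 at EB8, Puf60_pEx5_HOM 767 at ESC, 467 at EB8 and 687 at DIV7, Puf60_pEx5_HET 8 at ESC, the homozygous lines 811 at ESC, 2186 at EB8 and 801 at DIV7. Voom weights moved 9 of 17: Puf60_mEx5_HOM 533 at EB8, Puf60_pEx5_HOM 633 at ESC, 423 at EB8 and 583 at DIV7, Puf60_pEx5_HET 9 at EB8, Rbm38KO 20 at DIV7, the homozygous lines 705 at ESC, 2196 at EB8 and 656 at DIV7. The cause was not tested for these settings of limma. Fitting 1 stage alone, on fewer samples, gave Puf60_mEx5_HOM 10 at DIV7, Puf60_pEx5_HOM 113 at DIV7, Puf60_pEx5_HET 5 at DIV7, Rbm38KO 5 at DIV7, the homozygous lines 232 at DIV7. The authors' deposited table, a test on another measure and on 25359 genes, gave Puf60_mEx5_HOM 32 at ESC and 604 at EB8, Puf60_pEx5_HOM 995 at ESC, 614 at EB8 and 742 at DIV7. Among the 13714 genes in both, the authors' deposited table gave 18 and 470 for the former line and 739, 469 and 562 for the latter. Leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups, gave 9 to 11, 260 to 410, 2 to 5, 3 to 5 and 280 to 426 at ESC, 157 to 355, 182 to 303, 6 to 31, 5 to 9 and 1223 to 1582 at EB8, 34 to 212, 148 to 565, 16 to 237, 7 to 211 and 307 to 489 at DIV7 and 5515 to 5655 and 4027 to 4473 between WT stages.

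In place of the planned splicing fit, the log ratio of PSI called 9, 54, 17, 8 and 94 at ESC, 26, 91, 9, 21 and 289 at EB8, 15, 46, 12, 10 and 113 at DIV7 and 79 and 9 between WT stages. The read-weighted fit moved 12 of 17: Puf60_mEx5_HOM 74 at EB8 and 17 at DIV7, Puf60_pEx5_HOM 278 at ESC, 561 at EB8 and 279 at DIV7, Puf60_pEx5_HET 5 at ESC, 4 at EB8 and 3 at DIV7, Rbm38KO 1 at EB8, the homozygous lines 470 at ESC, 1699 at EB8 and 760 at DIV7. The comparison's libraries alone gave Puf60_mEx5_HOM 0 at EB8, Puf60_pEx5_HOM 0 at ESC and EB8, Rbm38KO 0 at EB8, the homozygous lines 0 at ESC, EB8 and DIV7. A minimum of 20 points gave Puf60_mEx5_HOM 0 at EB8, Puf60_pEx5_HOM 20 at EB8, Rbm38KO 3 at EB8, the homozygous lines 561 at EB8, WT from ESC to EB8 1309, WT from EB8 to DIV7 1458. Events with variable PSI gave Puf60_mEx5_HOM 0 at EB8, Puf60_pEx5_HOM 4 at EB8 and 1 at DIV7, Rbm38KO 1 at EB8, the homozygous lines 122 at DIV7, and 20 reads gave Rbm38KO 1 at EB8, the homozygous lines 25 at ESC. With 1 library left out the planned counts were 0 to 1, 0 to 2, 0, 0 and 1 to 6 at ESC, 0 to 9, 0 to 35, 0 to 13, 0 to 3 and 94 to 466 at EB8, 0 to 3, 0 to 3, 0, 0 to 3 and 2 to 15 at DIV7 and 1254 to 1847 and 717 to 1652 between WT stages.

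Within the read-weighted fit, 20 points gave Puf60_mEx5_HOM 36 at EB8 and 10 at DIV7, Puf60_pEx5_HOM 124 at ESC, 223 at EB8 and 140 at DIV7, Puf60_pEx5_HET 3 at ESC and 1 at DIV7, the homozygous lines 235 at ESC, 834 at EB8 and 343 at DIV7, WT from ESC to EB8 1368, WT from EB8 to DIV7 1634. Libraries of the comparison alone gave there Puf60_mEx5_HOM 1 at ESC, 140 at EB8 and 11 at DIV7, Puf60_pEx5_HOM 147 at DIV7, Puf60_pEx5_HET 5 at DIV7, Rbm38KO 7 at EB8 and 2 at DIV7, the homozygous lines 179 at ESC, and 20 reads Puf60_mEx5_HOM 112 at EB8. With 1 library left out its counts were 0 to 3, 79 to 152, 0 to 4, 0 to 3 and 212 to 254 at ESC, 2 to 45, 164 to 351, 0 to 10, 0 to 7 and 968 to 1210 at EB8, 2 to 13, 104 to 128, 1, 0 to 1 and 370 to 501 at DIV7 and 1826 to 2343 and 1959 to 2437 between WT stages. Apart from stricter minimums and fewer samples, the cause was not tested.

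A replicate block within stages, where the letters pair all groups at ESC and some at EB8 and DIV7, moved 1 of 17 gene counts (Puf60_mEx5_HOM 17 at ESC). In the planned splicing fit the block gave Puf60_mEx5_HOM 0 at EB8, Puf60_pEx5_HOM 0 at EB8, Rbm38KO 0 at EB8, the homozygous lines 1 at ESC and 4 at DIV7, and in the read-weighted fit Puf60_mEx5_HOM 2 at ESC and 116 at EB8. The block moved the interaction counts to Puf60_mEx5_HOM 1124 at EB8 and 48 at DIV7, Puf60_pEx5_HOM 2428 at DIV7, Puf60_pEx5_HET 4 at EB8 and 22 at DIV7, Rbm38KO 7 at EB8 and 13 at DIV7. It gave 157 list calls, 151 of them among the 156, and at ESC p53 targets in Puf60_pEx5_HOM went from an adjusted p of 0.0468 to 0.0733 and matrix genes in Rbm38KO from 0.122 to 0.033. At ESC it changed no other list call and no call of a named gene or event, and the cause was not tested.

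Overlaps of called genes, in the order opposite calls in the homozygous lines at EB8, then lower genes at DIV7 in both Puf60_pEx5 lines, in Puf60_pEx5_HOM with Rbm38KO and in Puf60_pEx5_HET with Rbm38KO, were 77, 65, 31 and 30. They were 77, 1, 0 and 1 with the stage alone, 156, 43, 14 and 14 with voom weights, 873, 119, 52 and 45 with no fold minimum and 170, 71, 28 and 23 with a pseudocount of 0.1. With 1 library left out they ranged from 59 to 97, 7 to 203, 3 to 166 and 3 to 150, and the cause was not tested.

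Interaction counts were Puf60_pEx5_HET 6 at EB8 and 28 at DIV7, Rbm38KO 4 at EB8 and 7 at DIV7 with no filter, which tests more genes, and Puf60_mEx5_HOM 22 at DIV7, Rbm38KO 2 at DIV7 with quantile scaling, where the cause was not tested. With 1 library left out they were Puf60_mEx5_HOM 170 to 577 at EB8 and 6 to 142 at DIV7, Puf60_pEx5_HOM 934 to 1297 at EB8 and 853 to 1687 at DIV7, Puf60_pEx5_HET 1 to 2 at EB8 and 6 to 190 at DIV7, Rbm38KO 1 to 3 at EB8 and 3 to 98 at DIV7.

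Calls were lost for 110 of 544 values of named genes with the stage alone, 46 of 546 with voom weights and 328 of 2184 with 1 library left out, and for named events with 1 library left out for 25 of 132 in the planned and 100 of 248 in the read-weighted fit. Named values changed sign as follows, with the range over left-out libraries, and the cause was not tested. Rbm38 in Puf60_mEx5_HOM at ESC was 0 without replicate B of WT and ranged from -0.11 without its own replicate A to 0.17. Puf60 in Puf60_pEx5_HOM at ESC was 0 with quantile scaling and -0.01 with scaling to the total. Without replicate B of WT at ESC, Puf60 and Rbm38 were -0.01 in Puf60_pEx5_HET and Puf60 was 0 in Rbm38KO, each up to 0.06. Rbm38 in Puf60_pEx5_HOM at EB8 was -0.03 without replicate B of WT and ranged from -0.1 without its own replicate B to 0.18, and at DIV7 from -0.01 without replicate B of WT to 0.33. Puf60 in Rbm38KO at EB8 was 0 with quantile scaling and ranged from -0.05 to 0.02 without replicate A of WT or its own replicate B. Rbm38 in Puf60_pEx5_HET at DIV7 was -0.01 without replicate B of WT and ranged from -0.19 without its own replicate B to 0.51. Puf60 from ESC to EB8 in WT was 0.53 with quantile scaling and 0.44 with scaling to the total. Exon 5 in Rbm38KO at EB8 ranged from -2.45 to 1.04 points against WT in both fits, the latter without replicate B of Rbm38KO.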

Other observations

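The tests of chromosomes and of the neighbours of Mid1 were chosen only after results were seen. For the 748 genes of chromosome 8 the median log2 fold changes in Puf60_mEx5_HOM, Puf60_pEx5_HOM, Puf60_pEx5_HET and Rbm38KO were 0.07, 0.11, 0.09 and 0.08 at ESC, 0.04, 0.01, 0.02 and 0.02 at EB8 and 0.03, 0.08, 0.07 and 0.05 at DIV7. For the 1174 genes of chromosome 11 they were 0.07, 0.11, 0.07 and 0.06, then 0.02, 0, 0.01 and -0.01, and 0.02, 0.07, 0.05 and 0.01. All 4 lines share the WT libraries. Next to Mid1, whose reads nearly vanished in Puf60_mEx5_HOM, Arhgap6, Hccs and Frmpd4 changed by 0.08, -0.03 and -0.05 at ESC, -0.39, 0.01 and -0.08 at EB8 and -0.58, 0.12 and 0.36 at DIV7. Genes on the other side of Mid1 and a link to the Y-linked genes were not tested.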
